A study of Mus musculus with 10 samples.

How the data were processed

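Strand-specific libraries of total RNA from 10 leukemic mouse spleens were compared, 5 from control mice and 5 from mice in which Sirt1 was deleted with tamoxifen. Per the labels' protocols, spleens were pressed through a filter, red cells were lysed, and RNA was taken up with QIAGEN kits. Per the submitters' processing notes, reads were quantified with kallisto 0.44.0 and normalized with DESeq (no version given) on build mm10. The deposited signal is a table of normalized counts, with 16865 gene symbols and 1 column per library. All 10 columns were used, so 0 columns were left out. The annotation, the filter on genes, the step from transcripts to genes and the use of strand in counting are not stated. Every listed gene had a value above 0 in at least 1 library, and the lowest sum of a gene over the libraries was 8.15.

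The values are not whole. In each library the lowest values lie near multiples of 1 step, from 76.8% to 88.1% of them within 0.1 of a step. The rest scatter by gene, as with a normalization factor for each gene and library, so whole reads could not be recovered for most genes and count models were not fitted. Dividing each total by its step gave the estimated depths in the results. Of the symbols, 20 had been turned into dates by a spreadsheet program and were kept as listed. GENCODE M21 (GRCm38) matched 16504 symbols and gave positions, with the length and GC content of the longest protein-coding transcript of each gene. These were known for 13304 of the tested genes (98.1%).

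A gene was tested where at least 5 libraries had a value of 10 or more, which left 13567. Values were compared as log2(value + 1) with limma 3.58.1 in R 4.3.3 (limma-trend), control against Sirt1 deleted, with no covariate. Adjusted p-values are Benjamini-Hochberg values over all genes tested, called at 0.05, and all tests are two-sided. Sirt1 was also tested by exact permutation of the 10 libraries. No gene's change is paired, since the labels match no control with a deleted sample. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

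The gene lists, the named-gene rule, the tests and the first group of alternatives were set before the data were examined. Of 41 lists with 790 entries, 756 entries were in the table and 38 lists had at least 5 tested genes. Mitochondrially encoded genes (0 tested), NK cells (4 tested) and mast cells and basophils (4 tested) were not tested as lists. Lists were compared with the other genes by camera with a preset inter-gene correlation of 0.01, with an estimated correlation and fry beside it, adjusted over the 38 lists and with Sirt1 left out of all. Members were also adjusted over each list alone. Named genes are Sirt1, then the 10 largest rises and 10 largest falls among called genes whose groups do not overlap and whose higher group mean is at least 100. Clone names, pseudogenes and antigen receptor segments were passed over. To these come the members with the smallest p in each called list (3, or 4 where a list has over 20), and the 2 smallest in each of the NOTCH1, MYC, p53, MYST and sirtuin lists. Some members that this rule names are not given here one by one but are counted with their lists. Other genes named were chosen after their values were seen, as further members or contrasts.

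These alternatives were pseudocounts of 0.5 and 5, no filter and a minimum of 50, TMM factors (computed from the published formula), equal totals, quantile normalization, robust limma, array weights, B cell markers or macrophage and neutrophil markers as a covariate, both other set tests, and leaving out each library. Further alternatives, chosen after the data were seen, were a length and GC correction, each library's length slope as a covariate, omission of the 3 libraries with the steepest length slopes, and the correction with that omission. The correction subtracted natural splines with 5 degrees of freedom on log2 transcript length and on GC content, fitted in each library to deviations from the gene means. Since the slopes differ between the groups, it also removes any true difference that follows length. It takes the longest protein-coding transcript of each gene, so it can enlarge or create a difference where a shorter one is expressed.

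The steps were tested on simulated libraries of the same size and spread, with every gene drawn independently. Without a length trend, limma called in the right direction 22 of 50 genes changed 1.25-fold, 42 of 50 changed 1.5-fold, 43 of 47 changed 2-fold and 49 of 49 changed 4-fold, and it called 7 of 13378 unchanged genes. With the length slopes of the real libraries, 1387 of 13372 unchanged genes were called without the correction and 7 of 13145 with it. In the set test, a list raised 1.25-fold had an adjusted p of 2.56e-21 and 0 of 38 unchanged lists were called. Independent genes cannot show how the set test treats lists whose members move together, such as ribosomal protein genes (estimated correlation 0.859). The simulated trend was linear in the same transcript lengths, with no slope on GC content. The runs therefore show only that the correction removes a trend of that form.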

Results

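RNA was measured in bulk by strand-specific sequencing of 10 leukemic spleens from C57BL/6 mice. Each spleen came from an irradiated recipient that had been injected intravenously with T cell acute lymphoblastic leukemia (T-ALL) in which Sirt1, the gene of a NAD-dependent protein deacetylase, can be deleted by tamoxifen. The control group held 5 libraries from mice given corn oil alone, and the Sirt1 deleted group held 5 libraries from mice given 3 mg of tamoxifen in corn oil. Tamoxifen and deletion therefore came together, and no group received tamoxifen without the deletion. Replicate numbers follow the order of the libraries in the series and pair no library with another. The labels name no batch and do not say which leukemia each recipient carried, so the p-values measure the spread between these samples only.

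The table listed 16865 gene symbols with normalized counts that summed to 33.6 M at least and 34.8 M at most per library. The steps between the lowest values put the depth at about 21.2 to 44.4 M reads per library, with 38.4 ± 6.37 M (SD, n = 5) in the control group and 31.7 ± 8.25 M in the Sirt1 deleted group (exact permutation p = 0.19). A normalized count of 100 rested on about 61.8 to 131 reads, which is a counting error of 12.7% to 8.74%. This error covers counting alone. Pearson correlations between libraries of 1 group lay between 0.982 and 0.990, and those between libraries of different groups between 0.978 and 0.99. The first principal component held 40.1% of the variance and separated the groups, with no control library above -4.17 and no Sirt1 deleted library below 6.05.

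Sirt1 (chromosome 10, 63319005 to 63381704, minus strand, GRCm38) was lower in the Sirt1 deleted group. Control libraries 1 to 5 held 1324, 1348, 1174, 1192 and 1126 normalized counts. Sirt1 deleted libraries 1 to 5 held 922, 824, 1071, 1061 and 710. The means were 1233 ± 97.6 and 918 ± 155 (SD, n = 5), a log2 difference of -0.44 (SE 0.107, exact permutation p = 0.00794, the smallest that 5 against 5 allows, and limma adjusted p = 0.0125). The deleted group thus kept 73.8% of the control level, and all 5 of its libraries lay below every control. Correction of every library for transcript length and GC content left -0.26 (exact permutation p = 0.00794). With each library's length trend as a covariate in limma the difference was -0.03 and no longer passed. Over the 21 alternatives p ranged from 0.000311 with array weights to 0.786 with that covariate, both from limma before adjustment, and came from exact permutation where the libraries were weighted alike without a covariate and robust limma was not used. It was also not past it without the 3 libraries of steepest trend (exact p = 0.0857). Among 200 genes of like length, GC content and level, 11.5% fell further than Sirt1. Values per gene cannot show the loss of a single exon.

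The comparison asks which transcripts differ in established T-ALL spleens when Sirt1 has been deleted. As lists, transcripts of ribosomal proteins, of the respiratory chain and of replication-dependent histones were called higher in the Sirt1 deleted group, and so were marker sets of B cells and neutrophils and the MHC class II genes. Genes of cholesterol and fatty acid synthesis and marker sets of macrophages and erythroid cells were called lower. The fixed sets of NOTCH1, MYC and p53 targets were not called. These 10 list calls rest on a preset correlation between genes; with an estimated one camera called 0 of 38 lists (0 at an unadjusted p under 0.05) and the rotation test fry called 2. Much of the difference between genes followed the length of the transcripts. Corrected for it, 6 of the 10 lists were called with the preset correlation. Of all 38 lists, 0 were then called with an estimated correlation (0 at an unadjusted p under 0.05). By fry 0 of the 38 were called (10 unadjusted, which are not the same 10 lists). The lists of the respiratory chain and MHC class II shrank and lost their calls; those of B cells (median 0.44 before, 0.46 after) and neutrophils (0.87 before, 0.64 after) lost theirs with most of the difference left.

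Of 13567 genes tested, 4344 (32%) passed an adjusted p of 0.05 in limma, 1973 higher and 2371 lower in the Sirt1 deleted group. Their median absolute log2 difference was 0.35. At least a 2-fold change was reached by 136 genes, 44 higher and 92 lower. Among the 4344, the groups did not overlap for 2095 genes, and over all tested genes the groups did not overlap for 16.5%, where chance gives 0.794%. Single libraries carried part of these counts. Without control library 1 the number of genes was 2335, without control library 2 it was 2200, and without Sirt1 deleted library 2 it was 2711. The number of 2-fold genes was 82 without control library 2. Nearly all calls ended in limma with B cell markers as a covariate (1 gene, 2342 at an unadjusted p under 0.05), with each library's length slope as a covariate (0 genes, 578 unadjusted) and without the 3 libraries of steepest length slope (3 genes, 3159 unadjusted). Among the 61 called genes of the naming rule, the median share of the log2 difference left was 80.8%, 40.8% and 77.9% in these settings. With the B cell markers or without the steepest libraries, a lost call was thus not in itself a lost difference. With the slope covariate the median gene lost most of its difference, and 6 of the 61 reversed. These genes were picked largely for their size or small p and do not stand for all 4344.

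Differences between the groups followed transcript length. Across 13304 genes the log2 difference had a Spearman rho of -0.58 with log2 transcript length and 0.33 with GC content; genes are not independent replicates. The median log2 difference was 0.24 in the quintile of shortest transcripts (up to 1675 bases) and -0.27 in the quintile of longest ones (over 4946 bases). Of the shortest, 40.8% were called higher and 1.16% lower, and of the longest, 51% were called lower and 1.77% higher. Each library's slope of log2 deviation on log2 length was 0.0734 ± 0.0465 in the control group and -0.0734 ± 0.0668 in the Sirt1 deleted group (SD, n = 5, exact permutation p = 0.00794). The slope on GC content was -0.553 ± 0.408 and 0.553 ± 0.703 (exact permutation p = 0.0238). The trend also varied inside each group, from 0.0012 in control library 5 to 0.115 in control library 1, and from -0.00922 in Sirt1 deleted library 1 to -0.182 in Sirt1 deleted library 5.

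**Figure D1:**
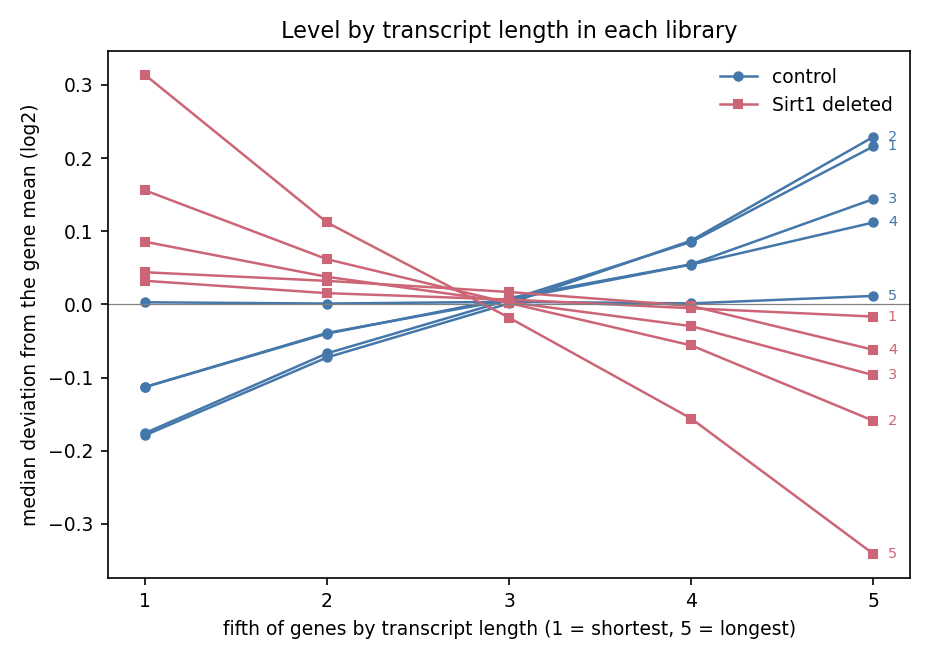
Median deviation of each library from the gene means (log2, y axis) in 5 equal groups of genes by transcript length (x axis, shortest at left), with 1 line per library, colored by group and numbered by replicate. In the longest transcripts control library 2 stands at 0.229 and Sirt1 deleted library 5 at -0.341, while control library 5 (0.0116) and Sirt1 deleted library 1 (-0.0166) lie close together.

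With length and GC content corrected in each library, 1910 of 13304 genes were called, 1103 higher and 807 lower, and 60 of them changed at least 2-fold. Of these, 1304 had been called in the same direction in the values as deposited, 8 in the opposite direction and 598 not at all. Some new calls may come from genes whose expressed transcript is shorter than the longest one used, which was not tested. Among the 4281 called genes with a known length, 2969 lost their call. Their median absolute log2 difference went from 0.32 to 0.10 and their median SE from 0.0880 to 0.0586, so the calls ended because the differences shrank.

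Clone-named genes, pseudogenes and antigen receptor segments were passed over in the ranking by size. Among the other called genes with at least 100 normalized counts in the higher group and groups that did not overlap, Tmem254b had the largest rise, from 256 ± 207 to 1076 ± 474 (log2 difference 2.34, adjusted p = 0.00855; chromosome 14, 26203369 to 26207041). Its reads are uncertain, because Tmem254a and Tmem254c are near copies. Phlda3 (chromosome 1, 135766119 to 135769136) rose from 66.7 ± 9.12 to 151 ± 27.8 (log2 difference 1.15, SE 0.144, adjusted p = 0.00797, corrected 0.80). Erdr1 rose by 1.12 and the ribosomal RNA precursor Rn45s by 0.94, and neither they nor Cd99 (0.77) have a length in the annotation to correct for. The histone genes Hist1h2bq and Hist1h2br, listed with identical values in all 10 libraries, rose by 0.90. Sap25 (0.88, corrected 0.55), Tgfbr3l (0.85) and Snora68 (0.82) completed the 10 largest rises, and Tgfbr3l lost its call after correction (0.39, adjusted p = 0.0767, within a range of 0.00412 to 0.999 over its alternatives).

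Within the same limits, Rabgap1 (chromosome 2, 37443279 to 37566454) had the largest fall, from 320 ± 224 to 24.8 ± 11.9 (log2 difference -3.31, SE 0.617, adjusted p = 0.00797). Its control libraries spread from 37.9 to 614. Cbl, which encodes a ubiquitin ligase, fell from 4552 ± 1346 to 1469 ± 716 (-1.73; chromosome 9, 44142976 to 44234049). Arel1 fell from 1902 ± 366 to 659 ± 335 (-1.72; chromosome 12, 84918148 to 84970900). The macrophage gene Adgre1 fell from 249 ± 116 to 87.3 ± 34.5 (-1.47, SE 0.304, adjusted p = 0.00855; chromosome 17, 57358691 to 57483527), and the Argonaute gene Ago2 from 4643 ± 1129 to 1736 ± 622 (-1.46; chromosome 15, 73095844 to 73184935). Megf9 (-1.46), Lmbrd2 (-1.43), Pdpr (-1.41), Lnpep (-1.40) and Fam46c (-1.35) followed. After correction Cbl stood at -1.34, Arel1 at -1.49, Adgre1 at -1.41 and Ago2 at -1.09, all still called. With the length slope as a covariate none of them was called in limma. Over the alternatives the smallest difference was -0.112 for Cbl, -0.0784 for Arel1, -0.266 for Ago2 and -0.991 for Adgre1. Control library 5 and Sirt1 deleted library 1 have the least steep length slopes of their groups. Cbl was 2678 and 2549 in them, and Adgre1 173 and 58.5. Applied to corrected values, the same rule shared 3 of the 10 rises and 4 of the 10 falls. A gene that left was not always smaller or uncalled. Tmem254b (corrected 2.19), Rabgap1 (corrected -3.08) and Cbl were still called at sizes within the ranking. They left through the condition that the groups do not overlap.

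**Figure D2:**
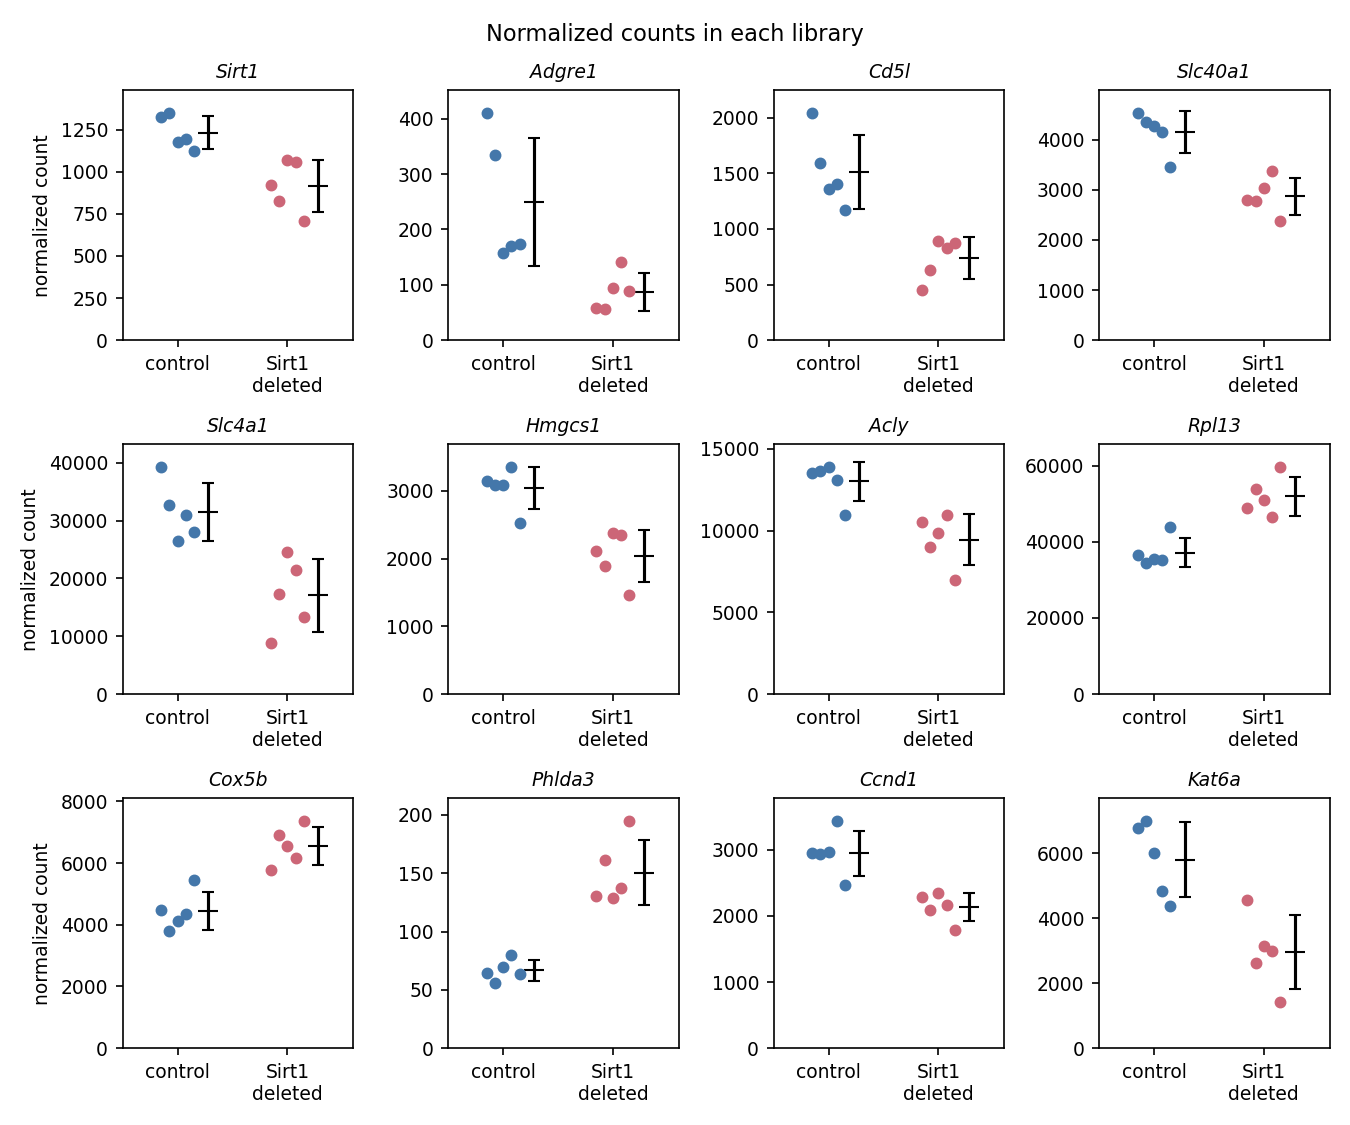
Normalized counts (y axis, from 0) of 12 genes in the 5 control and 5 Sirt1 deleted libraries. Points are libraries and bars are the group mean ± SD; all 5 Sirt1 deleted libraries lie below the lowest control for Sirt1 (1071 against 1126).

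Cytosolic ribosomal protein genes formed the most strongly called list (camera adjusted p = 9.23e-12). Of 38 tested, 32 rose, 0 fell and 6 did not pass; adjusted over the list alone, 36 rose. Their median log2 difference was 0.35, with an adjusted p = 0.874 with an estimated correlation. Rpl13 rose from 37146 ± 3880 to 51944 ± 5073 (0.48), Rps20 by 0.42, Rplp1 by 0.40 and Rps16 by 0.38, while Rpl3 was at 0.05 and did not pass (adjusted p = 0.48). The transcripts are short, with a median of 977.5 bases against 3001 for all tested genes. After correction Rpl13 (0.15) and Rplp1 (0.03) lost their calls, Rps16 stood at 0.17 and Rps20 at 0.55, both called. Rps20 was corrected at the 3706 bases of its longest transcript, against 499 for Rplp1, and its difference grew. If shorter Rps20 transcripts were counted, its corrected rise may be too large. The corrected median was 0.08, 9 members rose and the list was still called (adjusted p = 0.000516, in a range of 2e-13 to 0.874 over the alternatives, and 0.889 with correction and an estimated correlation together). With the length slope as a covariate the median reversed to -0.0093, and after quantile normalization it was 0.155, with the list still called.

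Of 31 nuclear-encoded genes of oxidative phosphorylation, 21 rose, 1 fell (Ndufs1, -0.18) and 9 did not pass; adjusted over the list alone, 22 rose and 1 fell. Their median was 0.25 (camera adjusted p = 8.33e-06, adjusted p = 0.874 with an estimated correlation). Cox5b rose by 0.57, Ndufa8 by 0.45, Atp5d by 0.43 and Ndufb5 by 0.31. After correction 12 members rose, among them Cox5b (0.33), Ndufa8 (0.16) and Atp5d (0.15) but not Ndufb5 (0.11), the median was 0.06 and the list was no longer called (adjusted p = 0.101, range 1.75e-06 to 0.874 over the alternatives). Of 21 replication-dependent histone genes, 8 rose, 0 fell and 13 did not pass; adjusted over the list alone, 10 rose. Their median was 0.66 (camera adjusted p = 1.87e-05, adjusted p = 0.874 with an estimated correlation). Hist1h3a rose by 1.03, Hist1h3c by 0.96, Hist1h4b by 0.89 and Hist1h3e by 0.67, and none of these 4 was called after correction. The list itself remained called, with a median of 0.32 and an adjusted p of 0.0154 (range 3.69e-07 to 0.874 over the alternatives, and 0.889 with both correction and an estimated correlation). Histone transcripts without a poly(A) tail are counted well only by some library types, and the labels do not give the selection used.

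The list of cholesterol synthesis was called lower. Of 24 genes, 12 fell, 1 rose (Ebp, 0.21) and 11 did not pass. Adjusted over the list alone, 13 fell and 2 rose. Log2 differences had a median of -0.24 (camera adjusted p = 0.0152, adjusted p = 0.874 with an estimated correlation). Hmgcs1 fell from 3036 ± 308 to 2036 ± 378 (-0.59) and Lss by 0.36. After correction 8 genes fell, Ebp was no longer called (0.09) and the median was -0.21 (adjusted p = 0.000196, range 3.53e-05 to 0.874 over the alternatives, and 0.889 with both correction and an estimated correlation). The median was -0.16 without Sirt1 deleted library 5, with the list still called. The call ended with the length slope as a covariate (median -0.0103, adjusted p = 0.464) and with the B cell markers as a covariate (median -0.119, adjusted p = 0.246). Of 13 genes of fatty acid synthesis and desaturation, 6 fell, 0 rose and 7 did not pass; adjusted over the list alone, 7 fell. Their median was -0.31 (camera adjusted p = 0.0177, adjusted p = 0.874 with an estimated correlation). Elovl6 fell by 0.58, Acaca by 0.55, and Acly from 13021 ± 1189 to 9456 ± 1578 (-0.47). After correction 3 genes fell, Elovl6 stood at -0.29, Acaca was no longer called (-0.20) and the list was still called with a median of -0.08 (adjusted p = 0.0154, range 0.0085 to 0.874 over the alternatives, and 0.889 with both correction and an estimated correlation). Its median reversed to 0.02 with the length slope as a covariate, and was -0.0999 over 15 genes without the filter on low values, with the list still called.

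The list of monocyte and macrophage markers was called lower by camera with the preset correlation, but not by fry (adjusted p = 0.0773). Of 18 genes, 8 fell, 1 rose (Ly6c2, 0.93) and 9 did not pass; adjusted over the list alone, 9 fell and 1 rose. Over all 18 the median log2 difference was -0.43 (camera adjusted p = 0.0104, adjusted p = 0.874 with an estimated correlation). Adgre1 has its values above. Cd5l fell from 1512 ± 332 to 736 ± 189 (-1.06), Slc40a1 from 4146 ± 414 to 2869 ± 369 (-0.53) and Marco from 359 ± 113 to 149 ± 68.2 (-1.34). Cd68 (0.13), Lyz2 (-0.17), C1qa (-0.18), C1qb (-0.43) and C1qc (-0.20) did not pass, and of these C1qb was called after correction (-0.73). After correction 7 genes fell, Ly6c2 was no longer called (0.68) and the median was -0.51 (adjusted p = 0.000121, range 6.95e-07 to 0.874 over the alternatives, and 0.889 with both correction and an estimated correlation). The list was called whichever library was left out.

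The list of erythroid genes was called lower, after a protocol that lysed red cells. Of 18, 5 fell, 0 rose and 13 did not pass, with the same counts adjusted over the list alone. As a list they had a median log2 difference of -0.38 (camera adjusted p = 0.0398, adjusted p = 0.993 with an estimated correlation). Slc4a1 fell from 31438 ± 4997 to 17105 ± 6332 (-0.95), the transferrin receptor gene Tfrc, which dividing cells of other types also express, by 0.64, and Alas2 by 0.59. Hbb-bs was at -0.48 and did not pass (adjusted p = 0.0794), but it was called after correction, at -0.76. After correction 7 genes fell, Tfrc stood at -0.39 and the median was -0.46 (adjusted p = 0.000196, range 6.95e-07 to 0.993 over the alternatives, and 0.889 with both correction and an estimated correlation). The call ended without control library 1 (adjusted p = 0.0685), control library 5 (0.215), Sirt1 deleted library 1 (0.221) or Sirt1 deleted library 5 (0.0517), and the median was -0.17 without Sirt1 deleted library 1.

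The list of B cell markers was called higher. Of 11, 4 rose, 0 fell and 7 did not pass, and the counts adjusted over the list alone were the same. The list had a median log2 difference of 0.44 (camera adjusted p = 0.029, adjusted p = 0.874 with an estimated correlation). Cd79a rose from 48.1 ± 8.55 to 89.4 ± 24.1 (0.85) and Fcmr by 0.65. Fcmr lost its call when any 1 library other than control library 5 and Sirt1 deleted library 3 was left out (adjusted p 0.0532 to 0.119), and it was not called after correction. The list lost its call without control library 5 (adjusted p = 0.101), Sirt1 deleted library 1 (0.0681) or Sirt1 deleted library 5 (0.0757). After correction its median was 0.46 (adjusted p = 0.0551, range 0.00762 to 0.982 over the alternatives).

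Of 10 genes of MHC class II antigen presentation, 4 rose, 0 fell and 6 did not pass; adjusted over the list alone, 5 rose. The median log2 difference was 0.30 (camera adjusted p = 0.029, adjusted p = 0.874 with an estimated correlation). Cd74 rose from 734 ± 82.8 to 1047 ± 175 (0.50), H2-Eb1 by 0.59 and H2-Ob by 0.67. H2-Ob lost its call without control libraries 1, 2, 4 or 5 or Sirt1 deleted libraries 2 or 3 (adjusted p 0.0512 to 0.0717). The list lost its call without control library 5 (adjusted p = 0.101) or Sirt1 deleted library 5 (0.0517). After correction Cd74 was no longer called (0.26), the list's median was 0.12 and it was not called (adjusted p = 0.349, range 0.0143 to 0.874 over the alternatives).

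Of 14 neutrophil genes, 2 rose, 0 fell and 12 did not pass; adjusted over the list alone, 0 passed in limma (8 at an unadjusted p under 0.05). At the list level the median log2 difference was 0.87 (camera adjusted p = 0.029, adjusted p = 0.988 with an estimated correlation). Retnlg rose from 75.9 ± 34.7 to 154 ± 52.3 (1.05) and S100a8 from 457 ± 221 to 863 ± 383 (0.94), and Ctsg was at 0.98 and did not pass (adjusted p = 0.0708). Retnlg lost its call without control libraries 1, 2 or 4 or Sirt1 deleted library 2 (adjusted p 0.0561 to 0.0674). S100a8 lost it without the same 4 libraries or Sirt1 deleted libraries 1 or 5 (0.0572 to 0.0975). Ctsg passed without Sirt1 deleted library 3 (adjusted p = 0.0132). The list was not called without control library 4 (adjusted p = 0.0686) or Sirt1 deleted library 1 (median 0.54, adjusted p = 0.194). After correction neither Retnlg (0.81) nor S100a8 (0.70) was called, and the list's median was 0.64 (adjusted p = 0.0978, range 0.00123 to 0.988 over the alternatives).

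Of 19 NOTCH1 targets, 4 rose and 4 fell; adjusted over the list alone, 5 rose and 5 fell. The median and mean log2 differences were -0.01 while the test pointed upward (camera adjusted p = 0.991, adjusted p = 0.993 with an estimated correlation). Ccnd1 fell from 2947 ± 342 to 2134 ± 217 (-0.46, corrected -0.39; chromosome 7, 144929931 to 144939925) and Il2ra by 0.42 (corrected -0.24). Notch1 fell by 0.32 (adjusted p = 0.025) and stood at -0.06 after correction, no longer called (adjusted p = 0.5). Of 28 MYC targets of ribosome biogenesis and growth, 7 rose and 4 fell; adjusted over the list alone, 8 rose and 4 fell. The median was 0.01, the mean was below 0 (-0.00161) and the test pointed upward (camera adjusted p = 0.796). Nme1 rose by 0.23 and Ddx21 fell by 0.40, which was -0.20 and not called after correction. Myc itself was at 0.20 and did not pass (adjusted p = 0.0535).

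Of 23 p53 targets, 5 rose and 2 fell, and the counts adjusted over the list alone were the same (median 0.11, camera adjusted p = 0.366). Phlda3 rose as given above. Bbc3 rose by 0.74 and Bax by 0.42; after correction Bbc3 was at 0.38 (adjusted p = 0.0544) and Bax at -0.01. Cdkn1a (0.22) and Mdm2 (-0.06) did not pass. Of 17 genes of MYST acetyltransferase complexes, 7 fell and 0 rose; adjusted over the list alone, 9 fell and 2 rose (median -0.19, camera adjusted p = 0.271). Kat6a fell from 5805 ± 1155 to 2953 ± 1136 (-1.05, corrected -0.69) and Jade1 by 0.55, which was -0.29 and not called after correction (adjusted p = 0.066). Kat7 was at -0.19 and did not pass (adjusted p = 0.0635). Of 18 genes of sirtuins and NAD metabolism, Sirt1 left out, 4 rose and 4 fell; adjusted over the list alone, 6 rose and 5 fell (median 0.15, camera adjusted p = 0.503). Sirt7 rose by 0.32 (corrected 0.10, not called, adjusted p = 0.151) and Cd38 fell by 0.66 (corrected -0.56).

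Lists of cell growth and division were not called. The median log2 difference was -0.05 for mitosis, where 5 of 24 genes rose and 4 fell, and 0.06 for DNA replication, where 6 of 28 rose and 2 fell. It was -0.02 for glycolysis (1 of 18 rose, 3 fell), -0.06 for hypoxia response (1 of 17 rose, 4 fell) and 0.02 for fatty acid oxidation and PPAR targets (3 of 21 rose). Of stress lists, the amino acid and integrated stress response had 4 of 21 genes higher and 3 lower, with a median of 0.05 and a mean of -0.07. The unfolded protein response had 3 of 19 higher and 4 lower, with a median of -0.02 and a test that pointed upward. In the heat shock list 0 of 12 passed in limma (3 at an unadjusted p under 0.05), and its median was -0.01. Autophagy and lysosome genes had 2 of 29 higher and 3 lower, with a median of 0.02 and a mean of -0.01. FOXO targets had 5 of 21 lower and 0 higher, with a median of -0.11 and the lowest adjusted p of the 28 lists not called (camera, 0.155). BCL2 family genes had 2 of 16 higher and 1 lower (median -0.05). Adjusted over the list alone, 5 mitosis genes fell, 5 replication genes rose, 5 hypoxia genes fell, 4 genes of the unfolded protein response rose, and 2 FOXO targets rose and 6 fell. In the same way 1 autophagy gene fell and 0 rose, and 0 genes of fatty acid oxidation passed (7 at an unadjusted p under 0.05 in limma). The other counts were the same.

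Among signaling and immune lists, NF-kB targets had 1 of 19 genes higher and 3 lower, with a mean of -0.10 and a test that pointed upward. Interferon response genes had 3 of 31 higher and 3 lower (median 0.08), and immediate early genes 6 of 19 higher and 0 lower (median 0.07, camera adjusted p = 0.271). Early T cell progenitor genes had 1 of 14 lower, with a median of 0.05 and a mean of -0.01. Genes of double-positive thymocytes had 6 of 20 lower and 1 higher (median -0.04). Among them Rag1 fell from 24641 ± 3882 to 15608 ± 2361 (-0.66, corrected -0.34). Mature and effector T cell genes had 2 of 19 higher and 2 lower (median 0.06), and T lineage genes 3 of 12 higher and 2 lower (median 0.15), with Cd3e at 0.07 and not passing. Adjusted over the list alone, 7 immediate early genes rose, 7 genes of double-positive thymocytes fell, 6 T lineage genes rose, and 1 mature and effector T cell gene rose and 1 fell. No early T cell progenitor gene passed that way (2 at an unadjusted p under 0.05 in limma), and the other counts were the same.

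Of the remaining cell type lists, plasma cell genes had 2 of 7 higher and 1 lower, with a mean of 0.21 and a median just below 0. Dendritic cell genes had 1 of 8 higher and 1 lower, with a median of -0.01 and a test that pointed upward. Of 8 megakaryocyte and platelet genes 0 passed in limma (0 at an unadjusted p under 0.05, median 0.07). Endothelial genes had 1 of 6 higher and 1 lower (median -0.15). Stromal genes had 1 of 5 lower, with a median of -0.08 and a mean of 0.01. Adjusted over the list alone, 2 endothelial genes rose, no dendritic cell gene fell, and the other counts were the same. All 28 lists without a call had camera adjusted p-values between 0.155 and 0.991. With an estimated correlation camera called 0 of the 38 lists, 0 of them at an unadjusted p under 0.05 (adjusted p 0.874 to 0.993), while the preset correlation called 10. The rotation test fry, which asks whether a list moves one way, called 2 lists, the histones and oxidative phosphorylation.

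**Figure D3:**
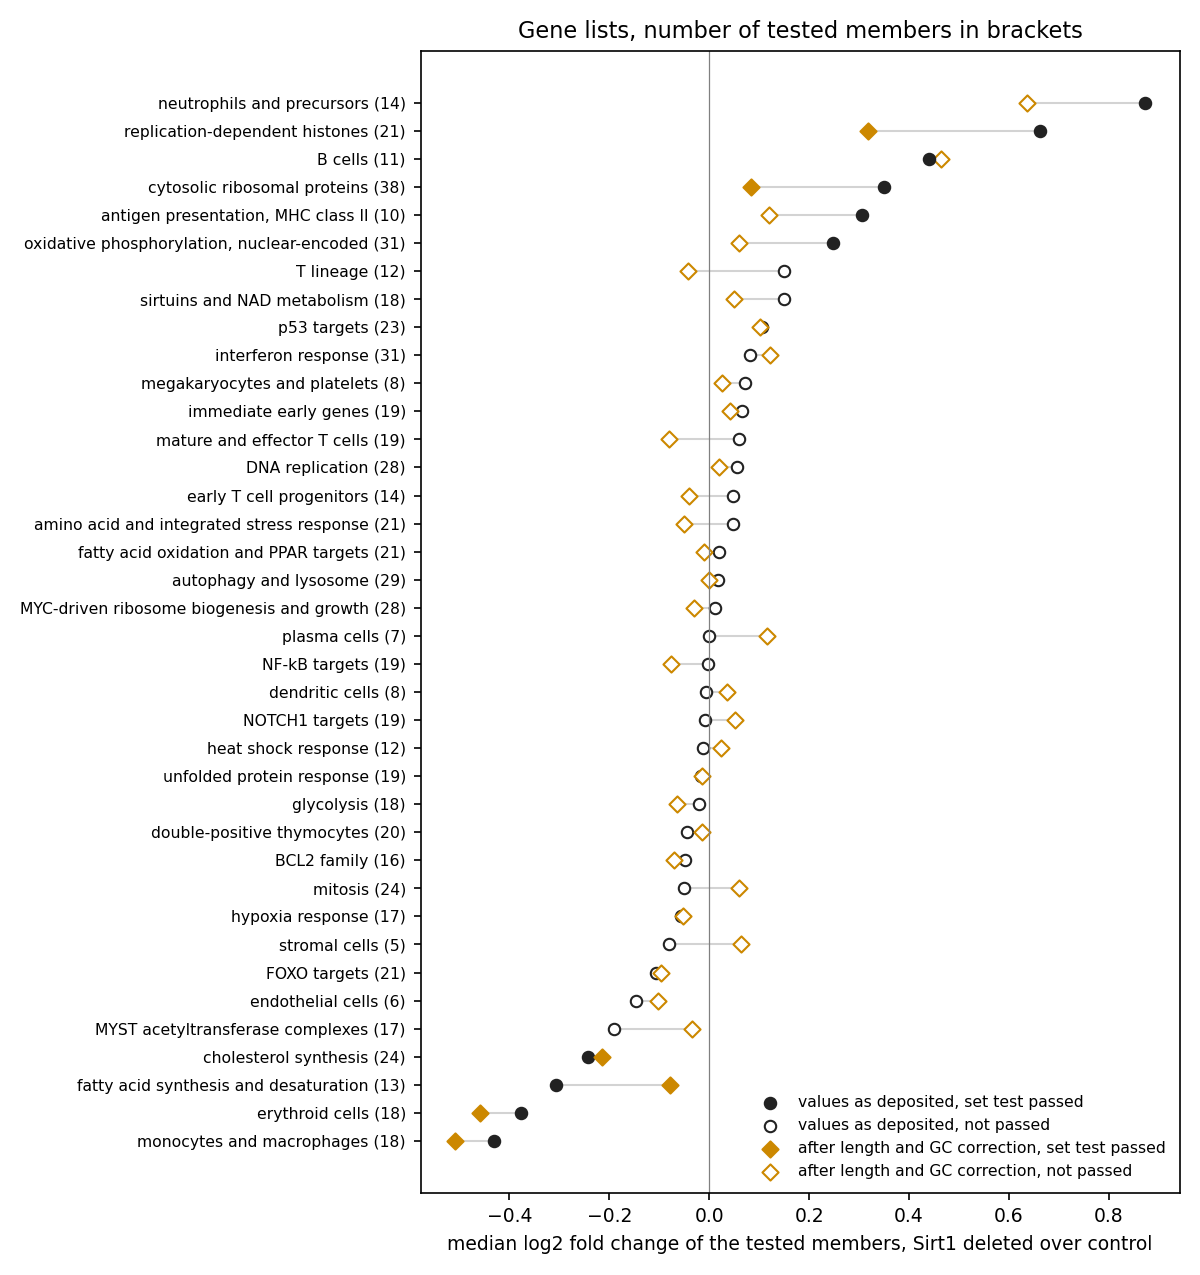
Median log2 difference (x axis, Sirt1 deleted minus control) of each of the 38 lists (y axis), as deposited (circles) and after correction for transcript length and GC content (diamonds). Filled symbols passed the set test; the macrophage list lies at -0.431 as deposited and -0.509 corrected, and the ribosomal protein list at 0.349 and 0.0846.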

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

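The tests written after the result was seen were the correction of the gene count, of Sirt1 and of the macrophage list for length and GC content, the comparison of B cell with macrophage markers, that of C1q with other macrophage markers, as deposited and corrected, and the orders of the length slopes. In 9 of 208 groups of 5 libraries tested, 1 library lay far from the other 4, with a gap over 0.71 of the whole range; chance alone gives about 10. Rpl13 was 43960 normalized counts in control library 5, with the nearest other control at 36480, and Rps16 was 44810 there against 39730. Acly was 10960 in control library 5 against 13090. Cd79a was 62.72 in control library 4, and the nearest other control held 46.92. As mean log2 level of a list, sirtuins and NAD metabolism stood at 9.7 in control library 5 (nearest 9.647) and fatty acid synthesis and desaturation at 11.33 there (nearest 11.55). Genes of fatty acid oxidation and PPAR targets stood at 10.36 in Sirt1 deleted library 4 (nearest 10.43), the unfolded protein response at 11.81 in control library 3 (nearest 11.91), and mature and effector T cells at 7.03 in control library 1 (nearest 7.208). Control library 5 is also the control with the length slope nearest to 0.

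The number of genes changed was larger for the real grouping than for other splits of the libraries into 5 and 5. The real grouping gave 4344 genes and the highest other split 2182 (1 of 100 splits as large, the real one included). A chance division of these libraries would thus rarely give this count, and 1 of 100 is the lowest share that the splits allow. The same holds for the 2-fold count (136, highest other 61, 1 of 100) and for the count after correction (1910, highest other 878, 1 of 100). The splits treat the libraries as exchangeable, and the labels name no batch. Chance stays open for the number of lists, which was 10 with a highest other of 13 (13 of 100 splits as large). It also stays open after correction, with 6 lists and a highest other of 12 (66 of 100). The split with 2182 genes set controls 1 to 4 and Sirt1 deleted library 4 against the rest.

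The first pattern is the count of genes changed. The correction left 1910, above the 878 of the highest other split drawn on the corrected values, so what remained still followed the grouping. This cannot decide whether the length and GC trend is the whole cause, because the fitted curves may not remove all of it. B cell minus macrophage markers differed between the groups by 0.892 (log2, exact permutation p = 0.00794), so these markers did not move together. Both lists had already been called, in opposite directions, in the same libraries. The contrast is therefore no separate evidence on the share of non-leukemic cells. A gradient between libraries that also runs inside the control group (each gene's slope on those libraries' length slopes) stays open: after correction its rho across genes with the group difference was -0.509, the strongest of 120 orders of the slopes (exact permutation p = 0.00833, closest other -0.506; genes are not independent replicates). With the gradient inside the Sirt1 deleted group, which shares no library with it, the rho was 0.321 (exact permutation p = 0.025), while that gradient's own rho with the group difference was -0.451 (17 of 120 orders as strong, exact permutation p = 0.142). Such a gradient could come from RNA quality, library preparation or the stage of disease at collection, for which the labels give no values; Sirt1 loss, tamoxifen itself and the leukemia of origin also stay open, untested.

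The second pattern is the lower level of Sirt1 in the Sirt1 deleted group. After correction the log2 difference was -0.255, with an interval whose upper bound was -0.105. That cannot decide whether the length and GC trend is the whole cause, because the fitted curves may not remove all of it from Sirt1. The difference was -0.159 with the correction and without the 3 libraries of steepest length slope. It was -0.0332 with the length slope as a covariate, which takes up much of the group difference. Whether Sirt1 fell through deletion or with other genes of like length, GC content and level cannot be told apart, because 11.5% of 200 matched genes fell further and their median was -0.213. With 73.8% of the control level left, normal recipient cells in the spleen, incomplete deletion and a stable transcript without the deleted exon remain possible and were not tested.

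The third pattern is the lower level of monocyte and macrophage markers. The median of the list after correction was -0.509 (camera adjusted p = 0.000121 with the preset correlation, range 6.95e-07 to 0.874 over the alternatives, but 0.889 with correction and an estimated correlation together and 0.12 by fry). Fewer macrophages with an unchanged profile and a changed profile cannot be told apart: as deposited, C1qa, C1qb and C1qc lay 0.243 above the other 15 markers in their difference (log2, exact permutation p = 0.0714), and after correction the gap was -0.0583 (exact permutation p = 0.587). The corrected difference was -0.583 for the C1q genes and -0.525 for the other markers (exact permutation p = 0.00794 for each). As deposited it was -0.271 for the C1q genes (exact permutation p = 0.262) and -0.514 for the other markers (0.00794). The other markers thus changed little with the correction, which argues against the length and GC trend, as fitted, as the whole cause of their lower levels. The C1q fall passed only after correction and does not bear on this. In the control group the list's mean log2 level fell in the order of the length slopes, from 9.107 in library 1 to 8.658 in library 5. In the Sirt1 deleted group it was lowest in library 1 (7.881), whose slope is the least steep there. A gradient between libraries that the fitted curves do not remove therefore stays open here too. Whether the list differs from other genes depends on the correlation assumed. An effect of tamoxifen on recipient cells stays open, as no group received it without the deletion.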

How the results depend on the processing

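The length and GC correction, the length slope covariate and the omission of the 3 libraries with the steepest length slopes were chosen after the data were seen. No paired analysis was possible because the labels match no control library with a deleted one. The count-model tests set beforehand were not run because whole reads could not be recovered for most genes.

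Under both pseudocounts, no filter, TMM factors, equal totals, quantile normalization, robust limma, array weights and the macrophage and neutrophil covariate, the counts of genes (4049 to 5325), of 2-fold genes (97 to 196) and of lists (7 to 10, where recomputed) stayed within 1.5 times those reported. A minimum of 50 gave 71 genes at 2-fold, since genes of low level were no longer tested. Quantile normalization ended the calls of the MHC class II (median 0.317), B cell (0.391) and neutrophil (0.894) lists. The minimum of 50 ended those of MHC class II (0.305), neutrophils (0.674) and erythroid cells (-0.376), and the B cell list then had too few genes to test. No filter ended that of B cells (0.412). These lists thus lost their calls with most of the difference left. Leaving out 1 library gave 2200 to 4712 genes (2200 without control 2, 2335 without control 1, 2711 without Sirt1 deleted 2), 82 to 191 at 2-fold (82 without control 2), 7 to 10 lists and -0.499 to -0.351 for Sirt1.

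With the B cell markers as a covariate, limma called 1 gene (Tspan7) and 1 at 2-fold, with 2342 and 172 at an unadjusted p under 0.05, and camera called 4 lists. The cholesterol (median -0.119, adjusted p = 0.246), fatty acid (-0.169, 0.179), MHC class II (0.171, 0.379), neutrophil (0.563, 0.36) and erythroid (-0.098, 0.775) lists lost their calls. The ribosomal protein list was still called, at a median of 0.186. The B cell list reversed to -0.0585, as its own markers were the covariate. With an estimated correlation camera called 0 lists (0 unadjusted), and fry called 2 (14 unadjusted). The length and GC correction gave 1910 genes, 60 at 2-fold and 6 lists; the lost gene calls had smaller differences, while the B cell list lost its call at a median of 0.464. With the length slope as a covariate limma called 0 genes (578 unadjusted) and 0 at 2-fold (79 unadjusted), and Sirt1 stood at -0.0332. Camera called 6 lists, of which 4 were among the 10 called as deposited. The oxidative phosphorylation (median 0.0277, adjusted p = 0.261), MHC class II (0.00866, 0.736) and B cell (0.305, 0.258) lists lost their calls. Sap25 (-0.0111), Megf9 (0.282), Acly (0.0295), Ddx21 (0.048), Kat6a (0.143), Jade1 (0.123), the ribosomal protein list (-0.0093) and the fatty acid synthesis list (0.0193) reversed. These slopes differ between the groups with no overlap, so the covariate takes up much of the group difference. Without the 3 steepest libraries, limma called 3 genes (0610009E02Rik, Abcc3 and Tspan7, with 3159 unadjusted) and 2 at 2-fold (68 unadjusted), with Sirt1 at -0.271. Camera called 8 lists, and the neutrophil (median 0.493, adjusted p = 0.132) and erythroid (-0.347, 0.0842) lists lost their calls. Still called were the lists of ribosomal proteins (median 0.203), oxidative phosphorylation (0.147), fatty acid synthesis (-0.194) and MHC class II (0.164), all with smaller medians. With the correction as well limma called 2 genes (0610009E02Rik and Abcc3, with 2024 unadjusted) and 2 at 2-fold (49 unadjusted), with Sirt1 at -0.159. The other causes were not tested.

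Of 61 named genes past the threshold, 38 of the 57 with a known length kept their call after correction and 19 lost it. With the slope covariate 55 lost it and 6 reversed, and with the B cell covariate or without the steepest libraries all 61 lost it, each in its direction, with a median of 80.8% and 77.9% of the log2 difference left. The omission left only 7 libraries, while the B cell covariate was fitted to all 10. Since the median gene kept most of its difference in both settings, these lost calls alone do not show that it depends on the trend or on B cells. In every other setting with all 10 libraries at most 2 lost it, and leaving out 1 library ended 1 to 5 calls. Depth limits genes of low level: 100 normalized counts rested on as few as 61.8 reads, and genes near the filter, at a value of 10, rested on fewer still.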

Other observations

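These values were chosen after they were seen, and no explanation of them was tested. Tspan7 (chromosome X, 10485158 to 10596605) had the smallest adjusted p of any gene, falling from 375 ± 23.4 to 191 ± 18.9 normalized counts (SD, n = 5, log2 difference -0.97, SE 0.0894, limma adjusted p = 0.000805), with -0.63 after correction for length and GC content. The noncoding RNA 0610009E02Rik (chromosome 2, 26445696 to 26459390, plus strand) held 25.6 to 41.6 normalized counts in the control libraries and 153 to 2406 in the Sirt1 deleted ones (log2 difference 4.11, SE 0.53, adjusted p = 0.00797). It overlaps the end of Notch1, which lies on the minus strand (26457903 to 26516663), and how strand was used in counting is not stated, so reads of Notch1 cannot be ruled out as part of its value.

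Abcc3 held 51.1 to 112 normalized counts in the control libraries and was listed at 0 in 4 of the 5 Sirt1 deleted ones, with 75.2, inside the control range, in the other (adjusted p = 0.00855). The near copies Tmem254a, Tmem254b and Tmem254c summed to 1641 ± 59.0 in the control group and 2044 ± 197 in the Sirt1 deleted group (log2 difference 0.31, exact permutation p = 0.0159). Tmem254b alone rose by 2.34 while Tmem254c was at -0.67 and did not pass (adjusted p = 0.0743).

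At low levels, 4 genes picked by eye had groups that did not overlap. Krt14 rose from 20.7 ± 11.7 to 68.9 ± 35.5, Krt5 from 15.8 ± 7.53 to 39.8 ± 13.4, Acta1 from 18.8 ± 8.57 to 55.0 ± 14.6 and Myh1 from 9.76 ± 7.56 to 37.1 ± 15.3. Pdgfrb, on the fixed list of stromal markers, was at 24160 ± 1027 and 22535 ± 1940 beside Col1a1 at 87.5 ± 14.6 and 104 ± 7.90. Xist and genes of the Y chromosome were present together in all 10 libraries. Xist was at 2752 ± 489 in the control group and 2256 ± 463 in the Sirt1 deleted group, and Eif2s3y at 2027 ± 88.4 and 2132 ± 153.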
